A study of Zymomonas mobilis with 10 samples.

How the data were processed

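Hi-C, in which crosslinked DNA is cut, filled in with biotin, ligated and sequenced so that each read pair reports 2 places that lay close together, was carried out on Zymomonas mobilis, an ethanol-producing alphaproteobacterium. Cells in exponential phase were fixed with formaldehyde, the DNA was cut with Sau3AI and ligated in a diluted mix, and the libraries were read as pairs, per the labels' protocols. The 10 samples form 5 groups of 2. These are the wild-type strain ZM4 in condition RM, the genomic mutation strain ZM532 in RM, ZM532 under the environmental stress condition AF, and strains zur and zurfur in RM, which the submitters describe as carrying deletions of Fur proteins. Fur-family proteins are metal-sensing transcription regulators, and Zur is the family's zinc-sensing member. The labels used here do not spell out RM and AF, and do not name the parent of the deletion strains.

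The values are a corrected contact score per pair of 10 kb bins, deposited by the authors as 1 matrix per group. Each matrix covers 2060 kb, is symmetric and has no empty bin. Reads were trimmed with Trimmomatic, per the submitters' processing notes, and the matrices are iteratively corrected, per the labels. Iterative correction divides each bin pair by a factor per bin until all bins have the same sum, and the row sums within a matrix differed by at most 0.000287% of their mean. Coverage of a bin, and with it any check of the deleted genes by their copy number, is removed by this step. The aligner, the read filters, the treatment of the diagonal and the genome build are not given in the sources used here. The labels of both replicates of a group name the same matrix, so there is 1 pooled map per group. No replicate spread can be had, no test between groups was made and no p-value is given. Whether the replicates came from separate cultures is not stated.

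The row sums of the matrices ranged from 564275 in zurfur RM to 1876400 in ZM532 RM in the deposited score. These are not read counts, the depth is unknown, and no counting interval is given. As an upper bound on counting noise, the relative scatter of a bin pair around its neighbours on the same diagonal was taken at 300 to 990 kb. It was 1.87% in ZM4 RM, 2.02% in ZM532 RM, 2.07% in ZM532 AF, 4.62% in zur RM and 5.35% in zurfur RM. The bound was highest in the deletion maps, so single bin pairs may be least certain there, though the scatter can also hold real structure.

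From each matrix the diagonal was left out and the values were scaled to a mean row sum of 1, so that contacts are shares of a bin's contacts. Distances were circular, up to 1030 kb. Contacts were summed as local (10 to 50 kb), intermediate (60 to 200 kb) and long-range (over 200 kb). The shares of these classes sum to the whole, so their differences are not independent of each other. With no dependence on distance, 80.5% of contacts would be long-range and 4.88% local. The decay exponent is the slope of log10 mean contact on log10 distance. The insulation score of a bin is the log2 of the mean contact across it in a 100 kb window, relative to the chromosome mean, so that a low score marks few contacts across the bin. A domain boundary is a local minimum with a prominence of at least 0.1, and 2 boundaries within 1 bin of each other count as shared. Observed over expected is a bin pair's value over the mean at its distance. Map similarity is Pearson's r of its log2 over all bin pairs, which are not independent replicates. SDs given over bins describe spread along the chromosome and not error between replicates. The boundary caller was tested on simulated data with each map's decay and noise. It recovered all 8 simulated boundaries of 0.3 log2 contrast with 0 false ones in each of the 5 simulations, and called 0 in simulated maps without domains. At a contrast of 0.1 log2, closer to the domain strength of ZM4 RM, ZM532 RM and ZM532 AF, it recovered 7, 7 and 5 of the 8 with their decay and noise and 6 with those of each deletion map, with 0 false ones, so weak boundaries can be missed. The simulated noise was independent for each bin pair and was averaged within the window, far below the prominence limit. The counts of 0 false calls were thus all but fixed in advance. They do not gauge false boundaries from structure that neighbouring bin pairs share.

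Before the data were examined, 5 comparisons were fixed: ZM532 RM with ZM4 RM, ZM532 AF with ZM532 RM, zur RM and zurfur RM each with ZM4 RM, and zurfur RM with zur RM. The rule for named regions was fixed then too. It takes the 5 bins with the highest and the 5 with the lowest change in insulation score, the 3 with the highest and the 3 with the lowest change in long-range share, and boundaries with a prominence of at least 0.2 in 1 map and none within 3 bins in the other, skipping bins within 3 bins of one already taken. The most extreme of these are printed. Bins are named by their start in kb, in file order. Positions assume that the first bin starts at position 1 of the authors' chromosome sequence, which the files do not name. Gene lists had been planned, but the gene table used here belongs to another strain, CP4, so no gene was placed in a bin and no gene list was tested. Alternatives covered distance, scaling, correction, class limits, windows, prominence, tolerance, the reference map and 4 equal sections of the chromosome. The 1610 kb bin and the bins from 1890 to 1920 kb (1890001 to 1920000) were also left out, which was decided after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.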

Results

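Chromosome conformation was mapped in 5 groups of Zymomonas mobilis at 10 kb resolution, in bins spanning 2060 kb. Each 10 kb bin is named by the position in kb at which it starts. Each group was represented by 1 pooled map of its 2 samples, so differences between maps have no replicate check. The first and last bins were in close contact in all 5 maps, as on a closed circle. Their corrected score was 21366 in ZM4 RM, where neighbouring bins averaged 18076, and 40330 in zurfur RM, where neighbouring bins averaged 32415.

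The 5 maps differed in how steeply contacts declined with distance. Neighbouring bins made 2.70 times as many contacts as bins 940 to 1030 kb apart in ZM4 RM, 2.85 times in ZM532 RM, 4.44 times in ZM532 AF, 16.0 times in zur RM and 27.3 times in zurfur RM. Long-range contacts, over 200 kb, took 74.2% ± 0.68 (SD over bins) of all contacts in ZM4 RM, 73.4% ± 0.85 in ZM532 RM, 69.3% ± 1.32 in ZM532 AF, 54.1% ± 2.09 in zur RM and 44.6% ± 2.07 in zurfur RM. A chromosome with no dependence on distance would have 80.5%. Local contacts, at 10 to 50 kb, took 8.23% in ZM4 RM, 8.60% in ZM532 RM, 11.3% in ZM532 AF, 22.9% in zur RM and 30.0% in zurfur RM. The decay exponent over 20 to 200 kb was -0.18, -0.20, -0.32, -0.62 and -0.75 in the same order.

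**Figure D1:**
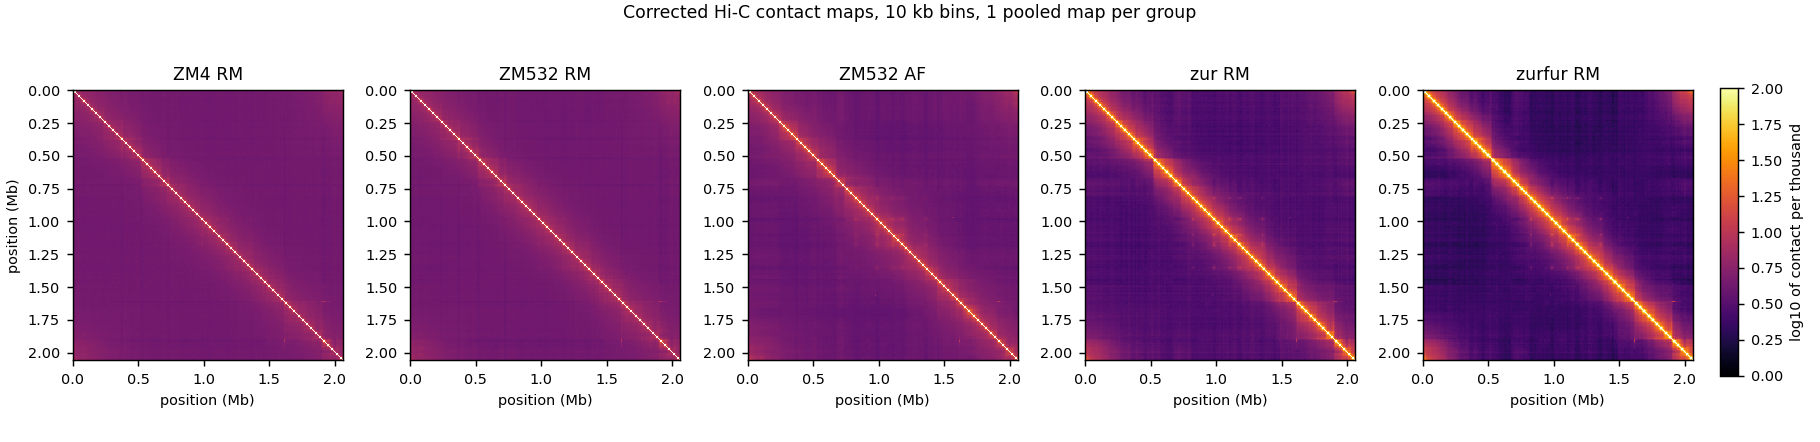
Corrected contact maps of the 5 groups, with position along the chromosome in Mb on both axes and colour giving log10 of 1000 times the share of a bin's contacts; the diagonal is left out. The deletion maps zur RM and zurfur RM have a brighter band near the diagonal and a darker far field than the other 3 maps.

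**Figure D2:**
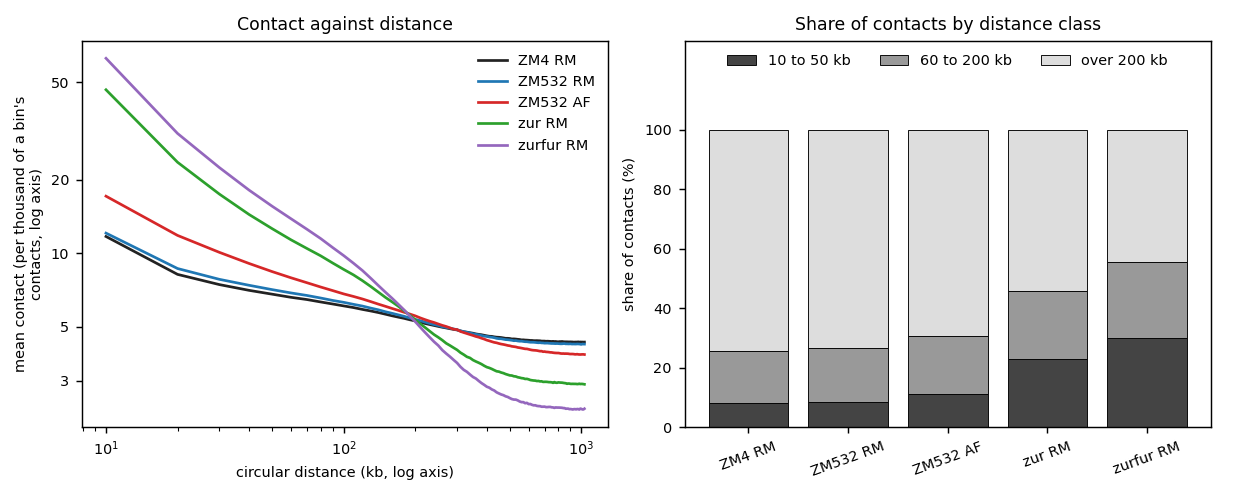
Left, 1000 times the mean share of a bin's contacts against circular distance in kb, both axes logarithmic, 1 line per pooled map; right, share of contacts in 3 distance classes in percent, with no error bars since each group has 1 map. Long-range contacts range from 74.2% in ZM4 RM to 44.6% in zurfur RM, and the curves of zur RM and zurfur RM first cross that of ZM4 RM at 210 and 200 kb.

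The first comparison asked what the mutations of ZM532 change in condition RM. The ZM532 RM and ZM4 RM maps were alike, with r = 0.88 over all bin pairs, r = 0.95 up to 200 kb and r = 0.97 between their insulation profiles. ZM532 RM had slightly more local contacts, 1.05 times the share in ZM4 RM, and this held in all bins. Contact was 1.06 times that of ZM4 RM at 20 kb, 1.03 times at 100 kb and 0.978 times at 1000 kb, with the curves crossing at 330 kb. The long-range share differed by -0.879 percentage points and was lower in all bins, a log2 ratio of -0.017 ± 0.0044 (SD over bins). The decay exponent differed by -0.017 over 20 to 200 kb, by -0.0034 over 10 to 100 kb and by -0.028 over 50 to 500 kb.

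Both maps had domain boundaries at the 520 kb bin (520001 to 530000) and the 1900 kb bin (1900001 to 1910000). The 1610 kb bin (1610001 to 1620000) was also a boundary in ZM4 RM with a prominence of 0.12. In ZM532 RM its insulation score was -0.060 against -0.078 in ZM4 RM, and it did not reach the prominence limit. The region with the lowest difference in insulation score was the 1440 kb bin (1440001 to 1450000), at -0.019 in ZM532 RM and 0.0015 in ZM4 RM. The same bin had the lowest difference in long-range share, 71.6% against 73.4%. The 370 kb bin (370001 to 380000) and the 1760 kb bin (1760001 to 1770000) followed in insulation score, with differences of -0.018 and -0.018. The highest differences were at the 540 kb bin (540001 to 550000), 0.025, and the 1570 kb bin (1570001 to 1580000), 0.023. All of these are small beside the range of the score in the deletion maps. Without scaling to equal totals the local log2 ratio was 0.32 against 0.064 and the long-range log2 ratio turned to 0.24, since the ZM532 RM matrix had the larger total, and with contacts under 60 kb left out it was -0.011.

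The second comparison set ZM532 under the environmental stress condition AF against the same strain in RM. Under AF, more of the contacts were local, and the pattern along the chromosome differed. Local contacts were 1.31 times those of ZM532 RM, a log2 ratio of 0.39 ± 0.11 (SD over bins), and were higher in all bins. Contact was 1.42 times that of ZM532 RM at 10 kb, 1.08 times at 100 kb and 0.910 times at 1000 kb, and the curves first crossed at 290 kb. The long-range share differed by -4.05 percentage points and the log2 ratio was -0.082 ± 0.026, lower in all bins but 1, and -0.039 with contacts under 60 kb left out. The exception was the 720 kb bin (720001 to 730000), with 71.9% under AF and 70.9% without. The bins with the lowest long-range difference were the 1710 kb bin (1710001 to 1720000), at 65.8% against 73.5%, the 1670 kb bin (1670001 to 1680000), at 66.2% against 73.7%, and the 980 kb bin (980001 to 990000), at 65.8% against 72.4%.

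After the decay with distance was divided out, ZM532 AF correlated over bin pairs with ZM532 RM at r = 0.49, with ZM4 RM at 0.47, with zur RM at 0.54 and with zurfur RM at 0.54. Scatter of single bin pairs can lower such an r, by an amount that differs between maps, so these values do not rank likeness. Averaged over 3 by 3 bins, r with ZM532 RM was 0.55, and no averaged value was computed for AF with the other maps. By insulation score the correlations were higher with its own strain, at r = 0.69 for ZM532 RM, 0.63 for ZM4 RM, 0.50 for zur RM and 0.48 for zurfur RM. ZM532 AF had 6 boundaries and ZM532 RM had 2. They shared 1, at the 1890 kb bin (1890001 to 1900000) under AF and the 1900 kb bin without. The 660 kb bin (660001 to 670000) was a boundary under AF and not without it, with a prominence of 0.29 and an insulation score of -0.17 against -0.043. The 1440 kb bin, with a prominence of 0.22 and a score of -0.12 against -0.019, was likewise a boundary under AF and not without it. The boundary of ZM532 RM at the 520 kb bin was not called under AF, where the score there was -0.052 against -0.095. The 730 kb bin (730001 to 740000) had the second lowest difference in insulation score, from -0.018 to -0.14. The highest differences were at the 1130 kb bin (1130001 to 1140000), from 0.033 to 0.11, and the 1080 kb bin (1080001 to 1090000), from 0.047 to 0.12. The SD of the insulation score over bins was 1.70 times that of ZM532 RM. Counted at a prominence of 1 SD of each map's own score, ZM532 AF had 10 boundaries, ZM532 RM had 7, and 6 were shared. The 660 and 1440 kb bins were then boundaries in ZM532 RM too, and AF had one next to the 520 kb bin. Without scaling to equal totals the log2 ratio was 0.19 for local and -0.28 for long-range contacts.

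**Figure D3:**
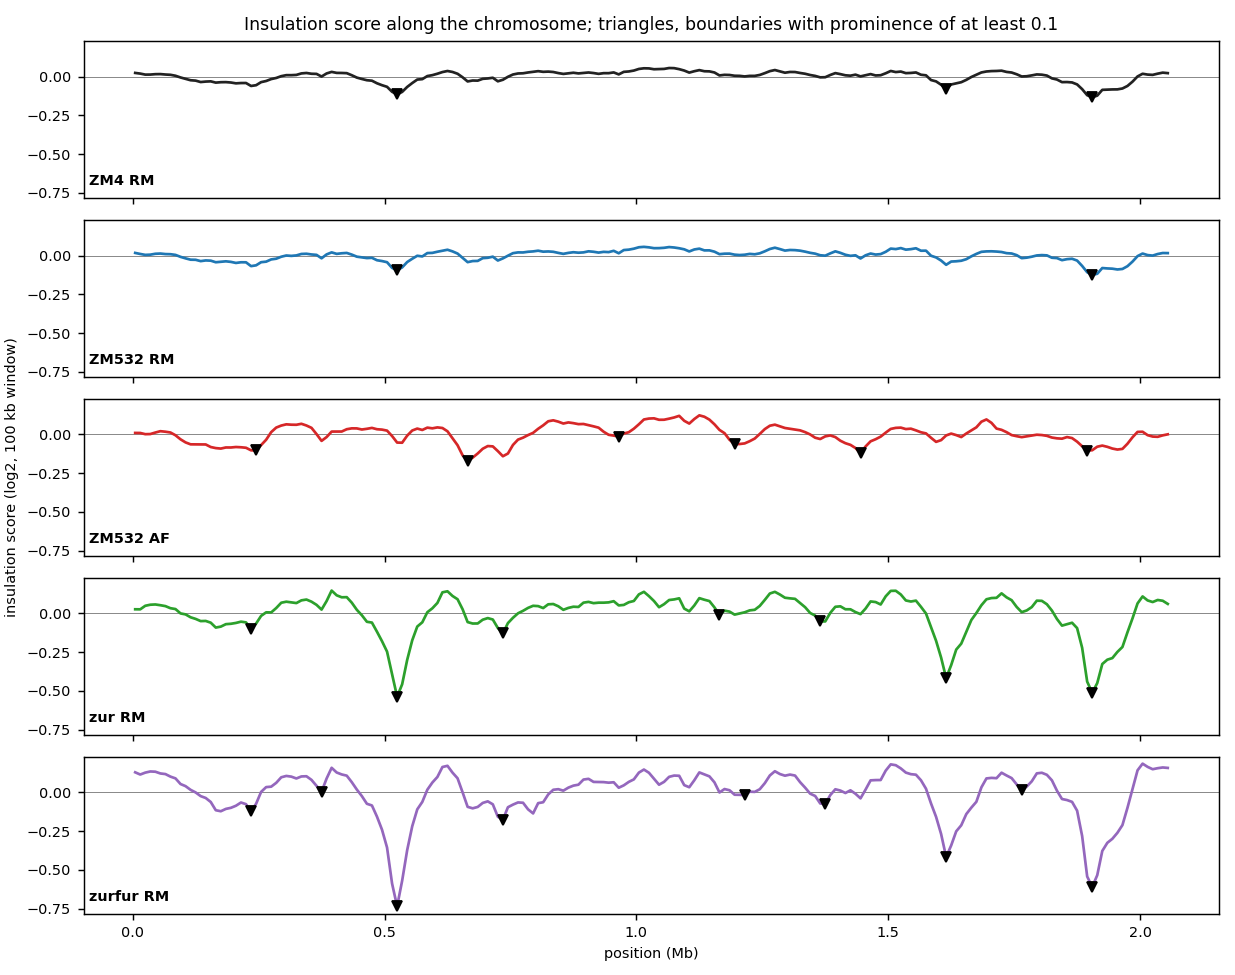
Insulation score (log2, 100 kb window) along the chromosome in Mb, 1 panel per pooled map, with triangles at boundaries of prominence at least 0.1. The minima at the 520, 1610 and 1900 kb bins reach -0.74, -0.42 and -0.61 in zurfur RM and -0.12, -0.078 and -0.13 in ZM4 RM, while ZM532 AF has its lowest score, -0.17, at the 660 kb bin.

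The third comparison asked what deletion of a Fur-family protein changes, with zur RM set against wild-type ZM4 RM. The zur map had 2.79 times the local contacts of ZM4 RM, a log2 ratio of 1.48 ± 0.10 (SD over bins), and 0.728 times its long-range contacts, a log2 ratio of -0.46 ± 0.049. Both directions held in all bins, but the shares of the distance classes sum to the whole, so they are not independent results. Contact was 3.99 times that of ZM4 RM at 10 kb, 1.41 times at 100 kb, 1.01 times at 200 kb, 0.706 times at 500 kb and 0.674 times at 1000 kb. The decay exponent differed by -0.44 over 20 to 200 kb and by -0.21 over 200 to 1000 kb.

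The 3 boundaries of ZM4 RM, at the 520, 1610 and 1900 kb bins, were all boundaries in zur RM, where they were deeper. The insulation score was -0.54 against -0.12 at the 520 kb bin, -0.42 against -0.078 at the 1610 kb bin and -0.51 against -0.13 at the 1900 kb bin. These were the 3 lowest differences among the named bins. The 230 kb bin (230001 to 240000), with a prominence of 0.21, and the 730 kb bin, with 0.27, were boundaries of zur RM with none near them in ZM4 RM. The highest differences in insulation score were at the 390 kb bin (390001 to 400000), 0.12, and the 1510 kb bin (1510001 to 1520000), 0.12. The long-range share differed least at the 1950 kb bin (1950001 to 1960000), 59.6% against 73.9%, and most at the 380 kb bin (380001 to 390000), 50.7% against 74.8%. zur RM had 7 boundaries in all and the SD of its insulation score was 3.47 times that of ZM4 RM. At a prominence of 1 SD of each map's own score, both maps had 7 boundaries and shared 5, and the 230 kb bin, but not the 730 kb bin, was then a boundary in ZM4 RM too. With contacts under 60 kb left out, the log2 ratio of the long-range share was -0.21. Without scaling to equal totals, the log2 ratio of the summed long-range scores was -1.62, with 0.32 for local contacts. The insulation profiles of the maps correlated with r = 0.92 over bins and the observed over expected values with r = 0.64 over bin pairs.

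The fourth comparison set zurfur RM against ZM4 RM, with differences in local and long-range share of the same sign and larger size. Local contacts were 3.64 times those of ZM4 RM, a log2 ratio of 1.86 ± 0.10 (SD over bins), and long-range contacts were 0.601 times, a log2 ratio of -0.74 ± 0.062. Contact was 5.36 times that of ZM4 RM at 10 kb, 0.993 times at 200 kb and 0.532 times at 1000 kb. The insulation score was -0.74 against -0.12 at the 520 kb bin, -0.61 against -0.13 at the 1900 kb bin and -0.42 against -0.078 at the 1610 kb bin. The 230, 730 and 1370 kb bins (1370001 to 1380000) were boundaries with prominences of 0.28, 0.35 and 0.22 that had none near them in ZM4 RM. The highest difference in insulation score was at the 2000 kb bin (2000001 to 2010000), from 0.018 to 0.19. The long-range share differed least at the 1900 kb bin, 52.1% against 74.2%, and most at the 1440 kb bin, 39.4% against 73.4%. zurfur RM had 9 boundaries. At a prominence of 1 SD of each map's own score it had 6, of which 5 were shared with ZM4 RM, the 730 kb bin being the exception. With contacts under 60 kb left out, the log2 ratio of the long-range share was -0.35. Without scaling to equal totals, the log2 ratio of the summed long-range scores was -2.32, with 0.28 for local contacts. The zur and zurfur comparisons share the ZM4 RM map, so their likeness is not independent evidence.

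The domains of ZM4 RM were marked more strongly in the deletion maps. Contacts at 20 to 100 kb within a ZM4 RM domain exceeded those between neighbouring domains by a log2 ratio of 0.13 in ZM4 RM, 0.11 in ZM532 RM, 0.088 in ZM532 AF, 0.59 in zur RM and 0.67 in zurfur RM. With the domains of each map itself it was 0.13 in ZM4 RM, 0.13 in ZM532 RM, 0.13 in ZM532 AF, 0.32 in zur RM and 0.30 in zurfur RM. Shared boundaries numbered 6, 6, 6, 6 and 18 in the 5 comparisons, in order, with a 50 kb window, 1, 0, 1, 1 and 3 with a 200 kb window, and 26, 19, 22, 18 and 22 by directional preference. In the order ZM4 RM, ZM532 RM, ZM532 AF, zur RM and zurfur RM, the 50 kb window called 6, 7, 12, 21 and 19 boundaries. The 200 kb window called 1, 1, 2, 3 and 4, and directional preference 32, 31, 23, 29 and 25. Few could thus be shared with ZM4 RM or ZM532 RM by the windows. Dense calls can match within 1 bin by position alone, and no chance level was computed. Antidiagonals were measured for contact between the chromosome's arms. The antidiagonal with the highest mean observed over expected reached a log2 value of 0.033 in ZM4 RM, 0.036 in ZM532 RM, 0.048 in ZM532 AF, 0.067 in zur RM and 0.13 in zurfur RM. It crossed the chromosome at about 35 and 1065 kb in ZM4 RM and ZM532 RM, 1000 and 2030 kb in ZM532 AF, and 60 and 1090 kb in both deletion maps. The lowest antidiagonals were of similar size, at -0.025, -0.022, -0.030, -0.072 and -0.13 in the same order, and the SD over antidiagonals was 0.016, 0.017, 0.024, 0.044 and 0.081.

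**Figure D4:**
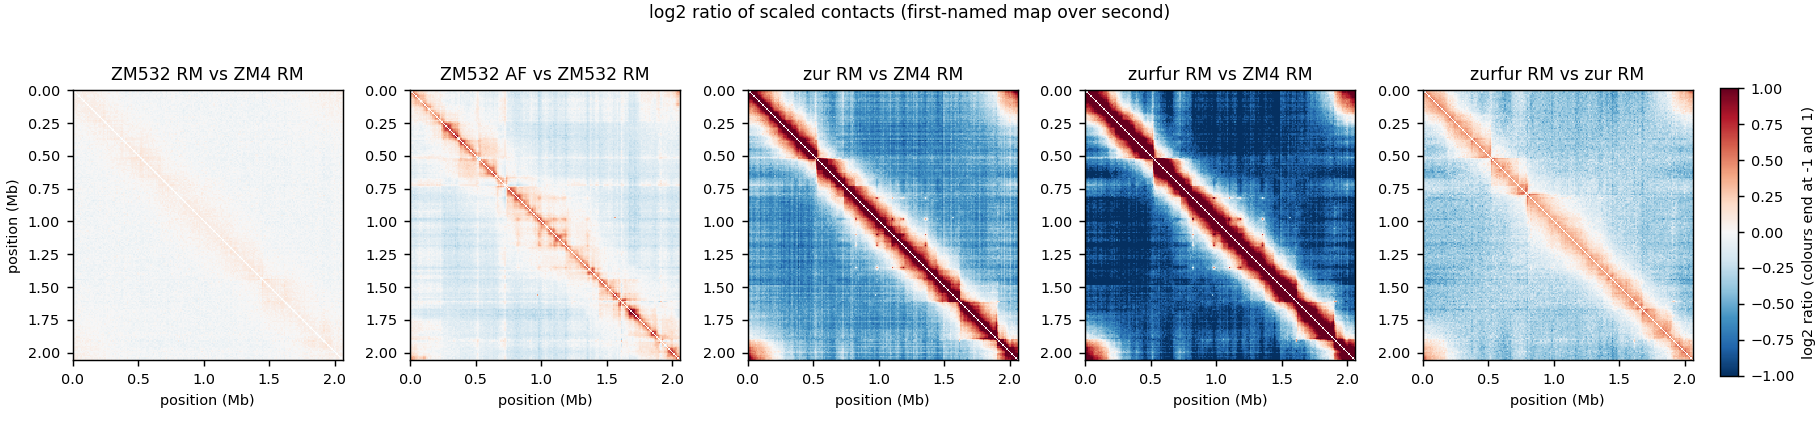
log2 ratio of scaled contacts for the 5 comparisons, first-named map over second, with position in Mb on both axes and colours ending at -1 and 1. ZM532 RM and ZM4 RM differ little, ZM532 AF shows blocks and stripes, and the deletion maps are higher than ZM4 RM near the diagonal and lower in the far field.

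The last comparison set the deletion strains against each other. The zurfur RM and zur RM maps were alike, with r = 0.89 over all bin pairs, r = 0.95 up to 200 kb and r = 0.97 between their insulation profiles. They shared 6 boundaries, against 18 with a 50 kb window, 3 with a 200 kb window and 11 at a prominence of 0.05. zurfur RM had 1.31 times the local contacts of zur RM and 0.825 times its long-range contacts, a log2 ratio of -0.28 ± 0.028 (SD over bins), lower in all bins and -0.14 with contacts under 60 kb left out. Contact was 1.35 times that of zur RM at 10 kb and 0.790 times at 1000 kb. The lowest differences in insulation score were at the 520 kb bin, from -0.54 to -0.74, and at the 790 kb bin (790001 to 800000), from 0.049 to -0.14. The highest difference was at the first bin (1 to 10000), from 0.027 to 0.13. The long-range share differed least at the 1900 kb bin, from 59.6% to 52.1%, and most at the 1670 kb bin, from 53.7% to 41.8%. Without scaling to equal totals, the log2 ratio of local contacts turned to -0.037 and that of long-range contacts was -0.70.

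The differences under AF were also set against those in the deletion strains, over bins and with no map in common. The log2 ratio of the long-range share under AF, bin by bin, correlated with that of zur RM against ZM4 RM with r = 0.41 and rho = 0.42, and with that of zurfur RM against ZM4 RM with r = 0.47 and rho = 0.46. Among all other circular rotations of the chromosome the highest r was 0.36 and 0.42, and the highest rho was 0.408 and 0.461, so that for zurfur RM a rotation exceeded the observed rho of 0.457. Neighbouring bins are not independent. With the profiles of both reference maps regressed out, r was 0.49 and 0.53. For the differences in insulation score the correlations were r = -0.051 for zur RM and -0.020 for zurfur RM, at the 43.9th and 47.8th percentile of rotations. Spearman's rho for these was 0.13 and 0.12, with the opposite sign, and with a 50 kb window r turned to 0.27 and 0.29. With the reference profiles regressed out of the insulation score differences, r was -0.19 and -0.090, at percentiles 13.2 and 27.8 of rotations.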

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

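The alternatives for the 1610 kb bin and the bins from 1890 to 1920 kb, for contacts under 60 kb, for a prominence of 1 SD and for averaging over 3 by 3 bins were chosen after seeing the data. No paired analysis was possible because each group's 2 replicates were pooled in 1 matrix, and for the same reason no replicate could be left out. Gene lists were not run for want of gene positions, and leaving out bins with deviating row sums removed 0 bins. With no replicates, a value was taken as moved when it changed by more than its SD over bins (shares), its jackknife error over 4 sections (exponents, correlations, domain strength), its SD over antidiagonals (arm contact) or by over 1.5 times (boundary counts). Of 67 alternatives for the long-range share, 41 stayed within this, and of 57 for the local share, 45 did. Leaving out any of 4 sections of the chromosome moved no share, and repeating the correction without the diagonal moved none. Except where a change of sign is given, shares, exponents and correlations kept their sign. Boundary counts depended on the window, the prominence and the caller. The cause of these shifts was not tested, apart from scaling, where the totals of the matrices differ. The depth is unknown, and the higher scatter of the deletion maps may limit single bin pairs there.

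Without scaling, the sums of scores are not shares and also carry the totals of the matrices. The log2 ratio of the summed long-range scores was then 0.24 for ZM532 RM against ZM4 RM, -0.28 for ZM532 AF against ZM532 RM, -1.62 for zur RM against ZM4 RM, -2.32 for zurfur RM against ZM4 RM and -0.70 for zurfur RM against zur RM. For over 100 kb, the log2 ratio of the long-range share was -0.010 for ZM532 RM against ZM4 RM, -0.35 for zur RM against ZM4 RM, -0.55 for zurfur RM against ZM4 RM and -0.20 for zurfur RM against zur RM. For over 300 kb, the log2 ratio of the long-range share was -0.022 for ZM532 RM against ZM4 RM, -0.51 for zur RM against ZM4 RM, -0.82 for zurfur RM against ZM4 RM and -0.31 for zurfur RM against zur RM. For over 500 kb, the log2 ratio of the long-range share was -0.026 for ZM532 RM against ZM4 RM, -0.12 for ZM532 AF against ZM532 RM, -0.55 for zur RM against ZM4 RM, -0.89 for zurfur RM against ZM4 RM and -0.34 for zurfur RM against zur RM. With contacts under 60 kb left out, the log2 ratio of the long-range share was -0.011 for ZM532 RM against ZM4 RM, -0.039 for ZM532 AF against ZM532 RM, -0.21 for zur RM against ZM4 RM, -0.35 for zurfur RM against ZM4 RM and -0.14 for zurfur RM against zur RM. With contacts at 10 kb left out, the log2 ratio of the long-range share was -0.35 for zur RM against ZM4 RM, -0.58 for zurfur RM against ZM4 RM and -0.23 for zurfur RM against zur RM.

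Without scaling, the log2 ratio of the summed local scores was 0.32 for ZM532 RM against ZM4 RM, 0.19 for ZM532 AF against ZM532 RM, 0.32 for zur RM against ZM4 RM, 0.28 for zurfur RM against ZM4 RM and -0.037 for zurfur RM against zur RM. With contacts at 10 kb left out, the log2 ratio of the local share was 1.31 for zur RM against ZM4 RM and 1.72 for zurfur RM against ZM4 RM. For 10 to 30 kb, the log2 ratio of the local share was 1.68 for zur RM against ZM4 RM and 2.09 for zurfur RM against ZM4 RM. For 10 to 100 kb, the log2 ratio of the local share was 1.17 for zur RM against ZM4 RM, 1.51 for zurfur RM against ZM4 RM and 0.34 for zurfur RM against zur RM.

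For 10 to 100 kb, the difference in decay exponent was -0.0034 for ZM532 RM against ZM4 RM, -0.13 for ZM532 AF against ZM532 RM, -0.45 for zur RM against ZM4 RM, -0.52 for zurfur RM against ZM4 RM and -0.072 for zurfur RM against zur RM. For 50 to 500 kb, the difference in decay exponent was -0.028 for ZM532 RM against ZM4 RM, -0.088 for ZM532 AF against ZM532 RM, -0.44 for zur RM against ZM4 RM, -0.66 for zurfur RM against ZM4 RM and -0.21 for zurfur RM against zur RM. For 20 to 500 kb, the difference in decay exponent was -0.024 for ZM532 RM against ZM4 RM, -0.10 for ZM532 AF against ZM532 RM, -0.44 for zur RM against ZM4 RM, -0.63 for zurfur RM against ZM4 RM and -0.18 for zurfur RM against zur RM. With median contact, the difference in decay exponent was -0.014 for ZM532 RM against ZM4 RM. With ZM532 RM in place of ZM4 RM, the difference in decay exponent was -0.42 for zur RM against ZM532 RM and -0.55 for zurfur RM against ZM532 RM. With linear distance, the difference in decay exponent was -0.58 for zurfur RM against ZM4 RM and -0.14 for zurfur RM against zur RM.

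With an insulation window of 50 kb, the number of shared boundaries was 6 for ZM532 RM against ZM4 RM, 6 for ZM532 AF against ZM532 RM, 6 for zur RM against ZM4 RM, 6 for zurfur RM against ZM4 RM and 18 for zurfur RM against zur RM. With an insulation window of 200 kb, the number of shared boundaries was 1 for ZM532 RM against ZM4 RM, 0 for ZM532 AF against ZM532 RM, 1 for zur RM against ZM4 RM, 1 for zurfur RM against ZM4 RM and 3 for zurfur RM against zur RM. ZM4 RM itself had 6 boundaries with the 50 kb window and 1 with the 200 kb window, which limits what could be shared. With a prominence of at least 0.2, the number of shared boundaries was 0 for ZM532 RM against ZM4 RM, 0 for ZM532 AF against ZM532 RM, 0 for zur RM against ZM4 RM and 0 for zurfur RM against ZM4 RM. At this limit ZM4 RM and ZM532 RM had 0 boundaries themselves, so none could be shared in these comparisons. With a prominence of at least 0.05, the number of shared boundaries was 5 for ZM532 RM against ZM4 RM, 5 for ZM532 AF against ZM532 RM and 11 for zurfur RM against zur RM. With boundaries called by directional preference, the number of shared boundaries was 26 for ZM532 RM against ZM4 RM, 19 for ZM532 AF against ZM532 RM, 22 for zur RM against ZM4 RM, 18 for zurfur RM against ZM4 RM and 22 for zurfur RM against zur RM. This caller gave 23 to 32 boundaries per map, and how many would match within 1 bin by position alone was not computed. With a prominence of at least 1 SD of the map, the number of shared boundaries was 6 for ZM532 RM against ZM4 RM, 6 for ZM532 AF against ZM532 RM, 5 for zur RM against ZM4 RM and 5 for zurfur RM against ZM4 RM. With the 1610 kb bin and the bins from 1890 to 1920 kb left out, the number of shared boundaries was 1 for ZM532 RM against ZM4 RM, 0 for ZM532 AF against ZM532 RM, 1 for zur RM against ZM4 RM and 1 for zurfur RM against ZM4 RM. With boundaries required in the same bin, the number of shared boundaries was 0 for ZM532 AF against ZM532 RM.

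For pairs up to 200 kb, the correlation between maps was 0.95 for ZM532 RM against ZM4 RM and 0.95 for zurfur RM against zur RM. For pairs over 200 kb, the correlation between maps was 0.83 for ZM532 RM against ZM4 RM and 0.86 for zurfur RM against zur RM. With Spearman's rho, the correlation between maps was 0.81 for ZM532 RM against ZM4 RM and 0.85 for zurfur RM against zur RM. Averaged over 3 by 3 bins, the correlation between maps was 0.96 for ZM532 RM against ZM4 RM, 0.77 for zur RM against ZM4 RM, 0.71 for zurfur RM against ZM4 RM and 0.93 for zurfur RM against zur RM.

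With the domains of ZM532 RM, the domain strength was 0.15 for ZM4 RM, 0.13 for ZM532 RM and 0.13 for ZM532 AF. For 20 to 200 kb, the domain strength was 0.10 for ZM4 RM, 0.087 for ZM532 RM, 0.037 for ZM532 AF, 0.41 for zur RM and 0.50 for zurfur RM. With the domains of the map itself, the domain strength was 0.13 for ZM532 RM, 0.13 for ZM532 AF, 0.32 for zur RM and 0.30 for zurfur RM.

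With an insulation window of 50 kb, the correlation of changes under AF was 0.27 for insulation score, zur RM and 0.29 for insulation score, zurfur RM. With an insulation window of 200 kb, the correlation of changes under AF was -0.21 for insulation score, zur RM.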

Other observations

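The tests below were chosen after the results they bear on had been seen, except the comparison of the share of the 1610 kb bin between maps, which was written down before that share was computed, and the correlation of the differences under AF with those of the deletion maps and its rotations, which were planned before the data were examined.

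Single bin pairs more than 220 kb apart that stood out from the ring of bin pairs around them, by over 6 robust SDs, were few. Of 16583 bin pairs, 9 stood out in ZM4 RM, 9 in ZM532 RM, 8 in ZM532 AF, 9 in zur RM and 9 in zurfur RM. In ZM4 RM all 9 involved the 1610 kb bin. In both deletion maps 3 did, and the others joined bins between 820 and 1570 kb. The robust SD in log2 was 0.026 in ZM4 RM, 0.028 in ZM532 RM, 0.031 in ZM532 AF, 0.070 in zur RM and 0.083 in zurfur RM. A pair thus needed a larger excess to stand out in the deletion maps, and the counts do not compare equal excesses. The 9 pairs of zur RM were the 9 of zurfur RM. The 980 kb bin (980001 to 990000) with the 1350 kb bin (1350001 to 1360000) had a log2 observed over expected of 0.13 in ZM4 RM, 0.17 in ZM532 RM, 0.40 in ZM532 AF, 0.87 in zur RM and 1.21 in zurfur RM. The 1100 kb bin (1100001 to 1110000) with the 1350 kb bin had 0.14, 0.18, 0.36, 0.92 and 1.13 in the same order. The 970 kb bin (970001 to 980000) with the 1560 kb bin (1560001 to 1570000) had 0.13, 0.092, 0.61, 0.43 and 0.60. ZM532 AF shared 6 of its 8 pairs with the deletion maps, ZM532 RM shared 4 of its 9 with each of them, and ZM4 RM 3 of its 9. With pairs of the 1610 kb bin left out, ZM532 AF had 4 pairs, all among the 6 of the deletion maps, where independent sets would share 0.0015, ZM532 RM had 1, also among them, and ZM4 RM had 0. In ZM4 RM the 970 and 1560 kb bins stood out by 5.40 robust SDs, just under the limit. The 980 and 1100 kb bins with the 1350 kb bin did so by 4.70 and 4.56. The 820 and 1180 kb bins did not, at -0.21. The count of 0 thus depends on the limit. Maps of the same species are not independent sets, so the expected number does not gauge a likeness of AF to the deletions. The log2 ratio of the long-range share under AF correlated with those of both deletion maps at the 100th percentile of rotations for Pearson's r. For Spearman's rho it was the 100th percentile with zur RM and the 99.5th with zurfur RM.

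The long-range share was lower in zur RM and zurfur RM than in ZM4 RM. Random ligation, as a uniform background in the ZM4 RM map alone, could lower its decay, but a line fitted over 200 kb then predicted 1.41 ± 0.020 (jackknife SE over 4 sections) times the observed ZM4 RM contact at 20 to 50 kb from zur RM and 1.54 ± 0.032 times from zurfur RM. Extra contacts between neighbouring fragments alone were argued against too, since with contacts under 60 kb left out the log2 ratio was -0.21 ± 0.030 (SD over bins) and -0.35 ± 0.043. Background in part, together with another difference, stays open, and so does a library batch, which cannot be told apart from strain with 1 map per strain and condition. The loss of Fur-family proteins, which the design names, stays open as an untested explanation.

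More boundaries were called in the deletion maps than in ZM4 RM, 7 in zur RM and 9 in zurfur RM against 3. Lower contrast of the ZM4 RM map with the same boundary positions may account for much of this, since at a prominence of 1 SD of each map's own insulation score there were 7 in zur RM, 6 in zurfur RM and 7 in ZM4 RM, of which 5 were shared in each case. At the 730 kb bin, which was not shared, the ZM4 RM prominence was 0.27 times that predicted from zur RM by the slope of the scores and 0.24 times that predicted from zurfur RM, and at the 1160 kb bin of zur RM it was 0.084 times. Bins without a boundary in ZM4 RM have low prominence by their choice, and directional preference called both in ZM4 RM, so whether contrast accounts for them stays open. What lowers the contrast was not tested, and an effect of the deletions on it stays open.

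The 1610 kb bin had raised contact with the bins from 1890 to 1920 kb (1890001 to 1920000) in all 5 maps, with a log2 observed over expected for the 1610 and 1910 kb bins of 0.93 in ZM4 RM, 0.84 in ZM532 RM, 1.12 in ZM532 AF, 1.32 in zur RM and 1.74 in zurfur RM. More bins stood out with the 1610 kb bin in ZM4 RM and ZM532 RM. There the 1840, 1920, 1930, 1940 and 1950 kb bins also did so, by over 6 robust SDs. In ZM532 AF the 1900, 1910, 1920 and 1930 kb bins did, and in the deletion maps only the 1890, 1900 and 1910 kb bins. The robust SD was larger there, at 0.070 in zur RM and 0.083 in zurfur RM against 0.026 in ZM4 RM. With the 1930 kb bin, log2 observed over expected was 0.31 in ZM4 RM, 0.16 in zur RM and 0.39 in zurfur RM. The number of bins that passed thus does not gauge the width of the raised region. If part of the 1610 kb bin lay beside the bins from 1890 to 1920 kb in every strain, or were repeated there, 1 share of its contacts might follow their distance curve in all maps, but the highest share, 38.95% in ZM4 RM, was 4.53 times the lowest, 8.59% in zurfur RM. Each share was taken from the map's own distance curve, which was steeper in the deletion maps. Observed over expected ran the other way and was highest in the deletion maps. The shares alone therefore do not settle whether part of the bin lies there in every strain. A joined end of a rearranged segment would bring either neighbour of that bin along, and the higher median ratio of their shares to that of the 1610 kb bin was 0.0704, with values up to 0.25 in zur RM and 0.14 in zurfur RM. A rearrangement or repeat that differs between strains, as the only cause of the different shares, was checked within ZM532. There the share was 33.03% in RM (27.6% to 35.2% with single bins left out) and 16.5% in AF (8.32% to 18.2%), 2.00 times apart. The distance curve was steeper in AF, with a decay exponent of -0.32 against -0.20 in RM, so these shares do not settle it either. Observed over expected was also lower in AF with the 1890 and 1900 kb bins, at 0.15 and 0.37 against 0.36 and 0.70. With the 1910 kb bin it was higher in AF. What raises this contact stays open, and no biological explanation was tested.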
